A study of Mus musculus with 8 samples.

How the data were processed

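RNA was measured by sequencing in 8 libraries of sorted mouse cells, 2 libraries in each of 4 groups. All came from naive mice carrying an Fgd5 ZsGreen reporter, in which a green fluorescent protein reports the Fgd5 locus. In the thymus, CD45+ cells with intermediate T cell receptor staining, CD1d staining and NK1.1 were sorted into reporter-positive (Fgd5+) and reporter-negative (Fgd5-) cells. In the bone marrow, reporter-positive CD45high EPCR- cells were sorted into CD5+CD244- and CD5-CD244+ cells. Groups were taken from the sample titles and the design text. Nothing in these sources says that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

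Per the labels' protocols, RNA was isolated with a Picopure kit and libraries were made with a SMARTer stranded total RNA kit, whereas the molecule label names polyA RNA. The submitters' processing notes name Trim Galore, STAR, HTSeq and the genome build GRCm38.p6. Their versions, the annotation release and the strand setting of the counting are not given in the sources used here. The deposited values are whole-number counts per gene, not normalized, in a separate table for each tissue. Each table listed 55487 gene identifiers, of which 55394 matched a symbol in a gene name table and 93 did not and kept their identifiers. Coordinates, transcript length and GC content came from a GENCODE annotation of GRCm38. The library names place the thymus and marrow libraries in different pools and flow cells, so tissue and sequencing run cannot be separated, and tests were made only within a tissue.

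Total counts per library were 14917749 and 14769491 for Fgd5+ thymus, 13296562 and 12434208 for Fgd5- thymus, 16064140 and 15667915 for CD5+CD244- marrow, and 16325771 and 17537443 for CD5-CD244+ marrow. The paired libraries of a group were compared by a chi-square of their counts over genes with at least 10 counts. It gave 7.24 to 14.3 per degree of freedom, far above the value near 1 that repeated sequencing of the same library would give, so no library was merged. Intervals and floors cover counting error only, because PCR reads without molecular identifiers are not independent molecules. A floor of 3 counts over the group was used for a gene with 0 counts in both libraries of a group, and a floor of 3 counts in each library for receptor segment shares.

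Differential expression was tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts. Libraries were scaled by TMM, genes were filtered with filterByExpr defaults, and a robust quasi-likelihood F test was fitted to the 4 libraries of each tissue without covariates. P-values were two-sided and adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Log2 fold changes are Fgd5+ over Fgd5- in the thymus and CD5+CD244- over CD5-CD244+ in the marrow. Their standard error (SE) is the size of the log2 fold change divided by the square root of F. CPM values, counts scaled to a common library size, use the TMM-scaled library sizes and are given as mean ± SD. With 2 libraries against 2, an exact permutation test of a single value cannot give a p below 0.333, so shares are given without a p.

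The design, the alternatives, the named genes and 27 gene lists were fixed before the data were examined. Lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01 between genes, two-sided and adjusted over the 27 lists of a comparison. They were tested again with a correlation estimated from the data and with fry. The estimated setting also tests on the few degrees of freedom that these libraries leave, so a lost call cannot be put down to correlation. Lists covered cytotoxic effectors, NK receptors, iNKT1, iNKT2 and iNKT17 markers, immature thymocyte markers, the T cell receptor complex and its signalling, gamma delta T and MAIT markers, and NK and ILC1 cell markers. Other lists held markers of stem and progenitor cells, B cells, plasma cells, neutrophils, monocytes and macrophages, dendritic cells, basophils and mast cells, eosinophils, erythroid cells, megakaryocytes, endothelium and stroma, and thymic epithelium. The remaining lists covered proliferation, interferon-stimulated genes, immediate early and dissociation stress genes, tissue residency and egress, and inhibitory receptors. A further fixed list and some named genes are not reported here. Lists share members, such as 14 of the 30 NK receptors and 9 of the 14 NK and ILC1 markers that stand in another list.

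Most named genes were chosen from these data by rule, by size of change or smallest p, so their values are selected extremes. The rule took the genes behind the sort, then the 6 largest changes in each direction. These needed an adjusted p under 0.05, a mean of at least 10 CPM and libraries that did not overlap between groups. Sort genes, predicted models, receptor segments and immunoglobulin genes were left out. From each list it took up to 4 members of smallest p, or 2 where none passed. Some further list members are named outside this rule, such as Prf1, Bcl2 and Cd3e in the thymus, and were not fixed in advance. Shares of T cell receptor segment counts were computed within each library.

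The tests were checked on simulated counts drawn from the real means and library sizes, with 100 genes changed by 2-fold and 100 by 4-fold. Changed genes were drawn only from those above a minimum mean CPM, so recovery of weaker genes was not measured. For the thymus (14191 genes fitted), 68% of the 2-fold and 97% of the 4-fold changes were recovered, and 0.093% of unchanged genes were called. For the marrow (15352 genes fitted), the values were 66%, 96% and 0.165%. A simulated moved list was called in each tissue, and 0 of 20 unmoved lists were called. Simulated genes varied independently, whereas the estimated correlation was 0.659 for thymus stress genes and 0.834 for marrow neutrophil markers. The simulation therefore does not show how often lists of correlated genes would be called falsely.

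Alternatives were RLE size factors, no count filter, a filter of at least 10 counts in 2 libraries, DESeq2 1.42.0, limma-voom with quality weights, no robust fitting and all 8 libraries in a single fit. Others were the replicate number as a block, removal of mitochondrial, haemoglobin and ribosomal RNA genes, a threshold of 0.01 and leaving out each library in turn. Thinning to the smallest library and offsets for GC content and length were chosen after seeing the data. Tables and plots used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, statsmodels 0.14.6 and matplotlib 3.10.9.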

Results

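Gene expression was counted in 4 thymus and 4 bone marrow libraries from naive Fgd5 ZsGreen reporter mice, with 2 libraries per group. The thymus comparison set Fgd5+ against Fgd5- cells of the same CD1d+ NK1.1+ gate, which the series title calls iNKT type 1 cells. Invariant natural killer T (iNKT) cells are T cells with a restricted receptor that sees lipid antigens on CD1d. The marrow comparison set CD5+CD244- against CD5-CD244+ cells, both reporter-positive. Libraries held 12434208 to 17537443 counts. Values below are mean CPM ± SD with n = 2 per group, and log2 fold changes ± SE with edgeR adjusted p-values.

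In the thymus, the genes behind the sort were read first as a check of the labels. Fgd5 (ENSMUSG00000034037, GRCm38 chromosome 6, 91978878 to 92076004), an exchange factor for Cdc42, stood at 173 ± 10.9 CPM in Fgd5+ libraries and 49.9 ± 1.71 CPM in Fgd5- libraries. Its log2 fold change was 1.79 ± 0.108 (edgeR adjusted p = 6.6e-08). Klrb1c, which encodes NK1.1, stood at 259 ± 9.71 CPM against 110 ± 8.87 CPM, a log2 fold change of 1.24 ± 0.091, although both sorts were gated on NK1.1. Ptprc, which encodes CD45, had a log2 fold change of -0.05 ± 0.056 and did not pass (edgeR adjusted p = 0.667). Gene models overlap Fgd5, Klrb1c and Ptprc on the same strand, so some of their reads may have been counted elsewhere or left out.

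Fgd5+ thymus libraries had higher RNA levels of killer-cell receptors and effector molecules than Fgd5- libraries of the same gate. The Fgd5- libraries may also hold other T cells, given their receptor segment shares below. These differences therefore need not be changes within the same kind of cell. Klra5 (ENSMUSG00000030173, chromosome 6, 129898996 to 129917650), a Ly49 receptor, rose from 12.6 ± 1.72 to 91.7 ± 8.58 CPM, a log2 fold change of 2.87 ± 0.165. The protease Gzma rose from 8.81 ± 1.98 to 44.4 ± 6.44 CPM (log2 fold change 2.33 ± 0.226), and the cytokine Ifng rose from 17.9 ± 8.22 to 72.8 ± 9.995 CPM (2.02 ± 0.253). Emp1, the transcription factor gene Maff and the small GTPase gene Gem completed the 6 largest rises, with log2 fold changes of 2.02 ± 0.263, 1.97 ± 0.245 and 1.96 ± 0.151. EdgeR adjusted p-values of these 6 genes lay between 5.2e-08 for Klra5 and 1.8e-04 for Ifng. A gene model, Gm49751, overlaps Ifng on the same strand. Ifng lost its call when all 8 libraries shared a fit (edgeR adjusted p = 0.0899).

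The largest falls under the naming rule included Ifngr2, Ccr7, Igfbp4, Acvrl1 and Adcy6. Ifngr2 (ENSMUSG00000022965, chromosome 16, 91547072 to 91565623), a chain of the interferon gamma receptor, had 1 count over both Fgd5+ libraries and 893 counts over both Fgd5- libraries, a ratio of 967 with an exact 95% counting interval of 173 to 38238. Ccr7, a chemokine receptor of naive T cells, was 0.247 ± 0.349 CPM against 70.7 ± 7.72 CPM (log2 fold change -8.13 ± 0.411). Adcy6, an adenylyl cyclase, was 2.02 ± 0.463 CPM against 99.1 ± 17.2 CPM (-5.61 ± 0.222), and Acvrl1 had a log2 fold change of -5.82 ± 0.413. EdgeR adjusted p-values of these genes ran from 9.6e-10 for Adcy6 to 3.7e-07 for Acvrl1. Igfbp4 had a log2 fold change of -6.23 ± 0.718 (edgeR adjusted p = 0.0237), and its call was lost without Fgd5- replicate 1 (adjusted p = 0.160), without Fgd5- replicate 2 (0.371) or with no count filter (0.214). Acvrl1 and Adcy6 have antisense gene models, whose reads cannot be told apart without a known strand setting.

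Across the 14950 genes tested in the thymus, 1006 were higher and 1011 lower in Fgd5+ libraries. The 2 libraries of each group did not overlap with those of the other group at any of the 2017 called genes. This held for 53.5% of all tested genes, against 33.3% by chance. Calls split 49.9% higher with TMM scaling and 60.4% higher once trends against GC content and transcript length were removed. The count of lower genes fell to 637 without Fgd5- replicate 1 and rose to 1614 without Fgd5+ replicate 2. Replicates correlated at 0.952 (Fgd5+) and 0.969 (Fgd5-) in log2 CPM across genes, and libraries of different groups at 0.917 to 0.930.

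**Figure D1:**
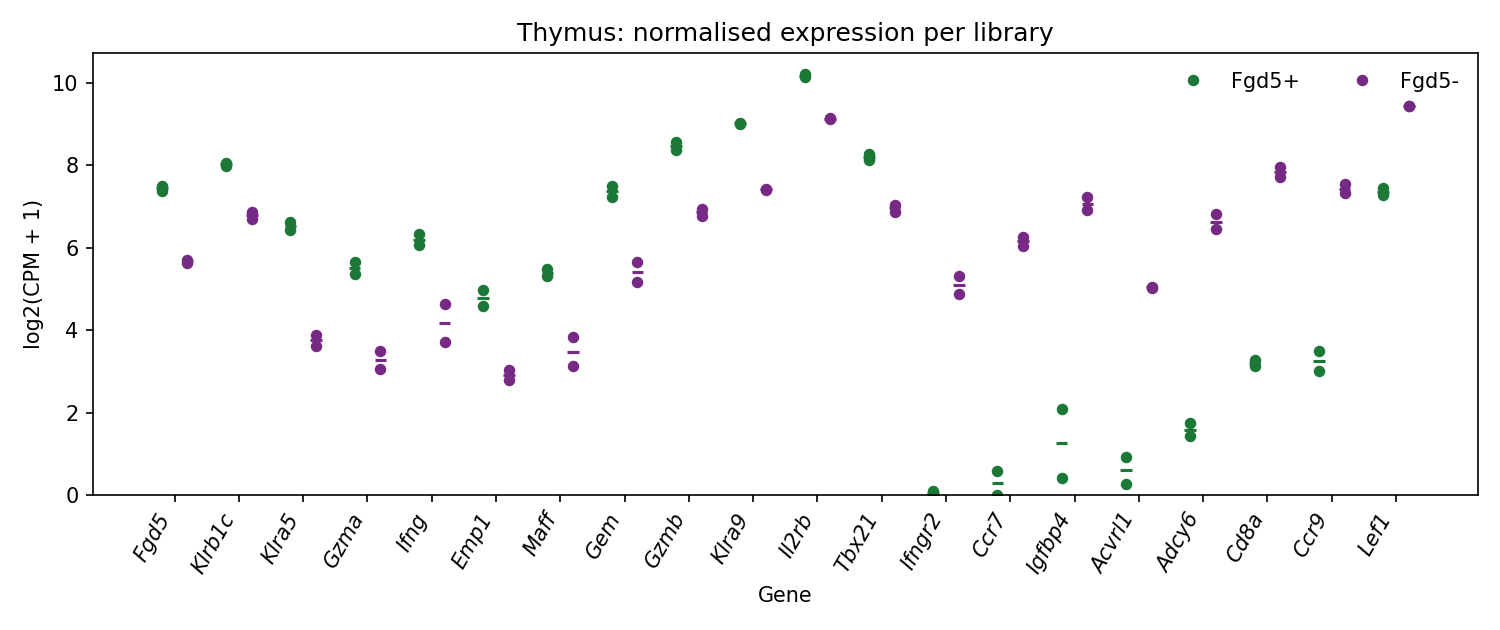
Normalised expression of named genes in the 4 thymus libraries, as log2(CPM + 1) with the gene on the x axis. Points are libraries, short lines are group means, green is Fgd5+ and purple is Fgd5-, and Klra5 stands at 91.7 CPM in Fgd5+ against 12.6 CPM in Fgd5- while Cd8a stands at 8.26 against 228 CPM.

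Cytotoxic effector genes rose as a group in Fgd5+ thymus libraries. Of 23 members tested, 16 rose, 0 fell and 7 did not pass, and adjusted over the list alone 19 rose and 1 fell. Gzmb, a granule protease, rose from 115 ± 10.2 to 353 ± 36.3 CPM (log2 fold change 1.62 ± 0.096). Slamf7 (1.06 ± 0.086), Fasl, the ligand of a death receptor (1.09 ± 0.110), and Serpinb9, a granzyme B inhibitor (1.46 ± 0.130), rose as well. The pore-forming Prf1 rose by a log2 fold change of 0.87 ± 0.130. The list test gave an adjusted p of 5.0e-24 by camera, and an adjusted p = 0.140 with an estimated correlation.

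NK receptor genes moved in the same direction. Of 29 tested, 20 rose, 0 fell and 9 did not pass, and adjusted over the list alone 20 rose and 2 fell. Klra9 rose from 169 ± 0.471 to 516 ± 2.14 CPM (log2 fold change 1.61 ± 0.073), Klra7 rose by 1.90 ± 0.102 and Klra13-ps by 1.48 ± 0.088. The Klra genes are near-identical copies that can share reads, so the split between members is uncertain. The camera adjusted p was 6.5e-35, and the adjusted p = 0.140 with an estimated correlation. NK and ILC1 cell markers had 7 of 11 tested members higher, 1 lower and 3 not passing, and adjusted over the list alone 7 rose and 2 fell (camera adjusted p = 1.2e-09; adjusted p = 0.140 with an estimated correlation). The member that fell was Eomes, a transcription factor of conventional NK cells, with 3 counts over both Fgd5+ libraries and 423 over both Fgd5- libraries (ratio 153, exact 95% counting interval 51.9 to 743). Ncr1, which encodes NKp46, had a log2 fold change of -1.99 ± 0.788 and did not pass (edgeR adjusted p = 0.123).

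Markers of the iNKT1 subset rose in 14 of 15 members, with 0 lower and 1 not passing, and adjusted over the list alone 14 rose and 0 fell. Il2rb, a receptor chain for IL-2 and IL-15, rose from 560 ± 2.07 to 1152 ± 44.6 CPM (log2 fold change 1.04 ± 0.062). Tbx21, which encodes T-bet, rose by 1.25 ± 0.092 and Id2 by 0.72 ± 0.073. Bcl2, the member that did not pass, had a log2 fold change of 0.04 ± 0.088. The camera adjusted p was 1.6e-24, and the adjusted p = 0.140 with an estimated correlation. Tbx21 lost its call when all 8 libraries shared a fit (edgeR adjusted p = 0.0567).

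Markers of the other iNKT subsets were lower on balance. Of 12 iNKT2 markers, 4 fell, 1 rose and 7 did not pass, with the same 4 and 1 adjusted over the list alone. Slamf6 fell by 3.57 ± 0.202 on the log2 scale, Il17rb by 3.24 ± 0.333 and Ccr4 by 2.79 ± 0.393. The member that rose was Zbtb16, which encodes PLZF (116 ± 9.99 to 221 ± 38.2 CPM). Of 14 iNKT17 markers, 6 fell, 1 rose and 7 did not pass, and adjusted over the list alone 6 fell and 1 rose. Rora fell by 1.21 ± 0.193 on the log2 scale, while the IL-7 receptor gene Il7r rose by 0.82 ± 0.089. Il23r had 2 counts in Fgd5+ libraries against 108 in Fgd5- libraries (ratio 58.5, exact 95% counting interval 15.8 to 489). The camera adjusted p-values were 0.00141 for iNKT2 and 0.00155 for iNKT17 markers, each with an adjusted p = 0.171 with an estimated correlation. The iNKT2 call was lost without Fgd5+ replicate 2 (camera adjusted p = 0.0617), and Il7r lost its call when all 8 libraries shared a fit (edgeR adjusted p = 0.132).

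Immature thymocyte markers formed the list with the smallest p in the thymus. Of 17 tested, 13 fell, 0 rose and 4 did not pass, and adjusted over the list alone 14 fell. Cd8a was 8.26 ± 0.615 CPM in Fgd5+ libraries and 228 ± 28.8 CPM in Fgd5- libraries (log2 fold change -4.79 ± 0.139), and Cd8b1 had -4.26 ± 0.148. Ccr9, a thymic homing receptor, had -4.31 ± 0.166, Cd4 -2.24 ± 0.091, Lef1 -2.09 ± 0.077 and the recombinase gene Rag1 -1.88 ± 0.121. The camera adjusted p was 5.6e-82, and the adjusted p = 0.0612 with an estimated correlation. Genes of the T cell receptor complex and its signalling had 9 of 22 members lower, 1 higher and 12 not passing, and adjusted over the list alone 13 fell and 1 rose (camera adjusted p = 3.1e-08; adjusted p = 0.140 with an estimated correlation). Tcf7 fell from 1001 ± 30.2 to 275 ± 21.5 CPM, and Bcl11b fell by 0.96 ± 0.072 on the log2 scale. Cd3e had a log2 fold change of 0.10 ± 0.064 and Cd3g 0.10 ± 0.065, and neither passed.

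Genes of proliferation were lower too, with 9 of 20 lower, 0 higher and 11 not passing, and 12 lower adjusted over the list alone (camera adjusted p = 5.5e-05; adjusted p = 0.259 with an estimated correlation). The fry test did not call that list (adjusted p = 0.0844). Plk1, a mitotic kinase, fell by 2.27 ± 0.400 and Rrm2 by 1.14 ± 0.243 on the log2 scale. Inhibitory receptors and exhaustion genes went both ways, with 3 higher, 3 lower and 5 not passing of 11, and 3 higher and 5 lower adjusted over the list alone (camera direction down, adjusted p = 0.0248; adjusted p = 0.239 with an estimated correlation). Tox, Cd200 and Pdcd1 had log2 fold changes of -1.62 ± 0.113, -4.04 ± 0.477 and -2.30 ± 0.325, and Entpd1 rose by 1.29 ± 0.138. That list's call was lost without Fgd5+ replicate 1 (camera adjusted p = 0.0582) or Fgd5- replicate 2 (0.120).

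Tissue residency and egress genes split in the thymus, with 9 higher, 3 lower and 4 not passing of 16, and 10 higher and 3 lower adjusted over the list alone. Besides the fall of Ccr7, the egress receptor S1pr1 fell by 1.48 ± 0.176 on the log2 scale. Itga1, a collagen-binding integrin chain, rose by 1.23 ± 0.101, and Zfp683, which encodes Hobit, rose by 0.99 ± 0.100. The list was not called (camera adjusted p = 0.205). Its median log2 fold change was 0.59 and its test pointed up, while its mean was -0.26. It was called without Fgd5- replicate 1 (camera adjusted p = 3.5e-04), Fgd5+ replicate 2 (0.00273) or Fgd5- replicate 2 (0.00349).

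Stress-related genes also differed between the thymus sorts, beside the effector and receptor lists. Of 19 immediate early and dissociation stress genes tested, 7 rose, 1 fell and 11 did not pass, and adjusted over the list alone 8 rose and 1 fell. Dusp1, a phosphatase, rose from 271 ± 67.2 to 882 ± 73.0 CPM, and the heat shock genes Hspa1a and Dnajb1 rose by 1.60 ± 0.164 and 0.89 ± 0.098 on the log2 scale. Btg2 rose by 0.87 ± 0.075, and Egr1 fell by 0.49 ± 0.123. The camera adjusted p was 1.3e-19, and the adjusted p = 0.222 with an estimated correlation. The fry test did not call the list (adjusted p = 0.0867). Hspa1a lost its call when all 8 libraries shared a fit (edgeR adjusted p = 0.124). Mitochondrially encoded genes took 7.80% and 7.96% of counts in Fgd5+ libraries and 6.99% and 7.70% in Fgd5- libraries. Most of this was mitochondrial ribosomal RNA, with 7.07% and 7.22% of counts against 6.34% and 6.98%.

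Several lists of markers of other cell types were called in the thymus on few tested members. Dendritic cell markers had 1 of 10 higher, 5 lower and 4 not passing, and 1 higher and 6 lower adjusted over the list alone (camera adjusted p = 1.3e-05; adjusted p = 0.171 with an estimated correlation). Their member of smallest p was Ccr9. Stem and progenitor markers had 2 of 5 lower and 0 higher, with 4 lower adjusted over the list alone (camera adjusted p = 0.00578; adjusted p = 0.211 with an estimated correlation), among them Slamf1 (-1.87 ± 0.222), which lost its call when all 8 libraries shared a fit (edgeR adjusted p = 0.195). Erythroid markers had 2 of 5 lower and 0 higher, and the same adjusted over the list alone (camera adjusted p = 0.0201; adjusted p = 0.259 with an estimated correlation). Among them, Car2 had 0 counts in Fgd5+ libraries and was at least 65.0-fold lower there, a call also lost in the fit of all 8 libraries (edgeR adjusted p = 0.137). Megakaryocyte markers had 2 of 4 lower and 0 higher, with 3 lower adjusted over the list alone, among them Itgb3 (-1.83 ± 0.116; camera adjusted p = 6.7e-04; adjusted p = 0.171 with an estimated correlation). The endothelial list rested on Pecam1 as its 1 tested member, lower also adjusted over the list alone (-2.16 ± 0.180; camera adjusted p = 1.8e-05; adjusted p = 0.171 with an estimated correlation). Monocyte markers had 1 of 5 higher and 0 lower, Ly6c2, with 2 higher adjusted over the list alone (camera adjusted p = 0.0250; adjusted p = 0.239 with an estimated correlation). Leaving out Fgd5+ replicate 2 ended the calls of the stem and progenitor (camera adjusted p = 0.458), erythroid (0.458), megakaryocyte (0.257), endothelial (0.230) and monocyte (0.182) lists. Leaving out Fgd5- replicate 1 ended those of the stem and progenitor (0.209), erythroid (0.209) and megakaryocyte (0.188) lists. Leaving out Fgd5- replicate 2 ended those of the stem and progenitor (0.235), megakaryocyte (0.125), endothelial (0.215) and monocyte (0.215) lists. The fry test also ended the monocyte (adjusted p = 0.0641) and erythroid (0.121) calls.

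Of the thymus lists not called, gamma delta T and MAIT markers had 3 of 9 higher and 2 lower (3 and 3 adjusted over the list alone), with log2 fold changes of 0.91 ± 0.162 for Tcrg-C2 and -1.97 ± 0.417 for Trdc. Their median log2 fold change was 0.18 and their test pointed up, while their mean was -0.65. Basophil and mast cell markers had 2 of 5 lower (1 higher and 3 lower adjusted over the list alone), and B lineage markers had 1 of 7 lower (1 adjusted over the list alone). Plasma cell markers had 1 of 5 lower, Irf4 (1 higher and 1 lower adjusted over the list alone). Their median was 0.02 and their mean -0.07, with the test pointing down. The neutrophil list had Gfi1 as its 1 tested member, lower, also adjusted over the list alone, and that call was lost without Fgd5- replicate 1 (edgeR adjusted p = 0.369). The eosinophil list had Ccr3 as its 1 tested member, which did not pass (lower adjusted over the list alone) and was called without Fgd5+ replicate 1 (edgeR adjusted p = 0.0444). The 2 thymic epithelial markers did not pass, also adjusted over the list alone. Interferon-stimulated genes had 3 of 18 lower and 0 higher (1 higher and 3 lower adjusted over the list alone). Camera adjusted p-values of these lists lay between 0.224 for the neutrophil list and 0.837 for gamma delta T and MAIT markers. The B lineage list was called without Fgd5+ replicate 2 (camera adjusted p = 0.0171) or Fgd5- replicate 2 (0.00398), and the interferon list without Fgd5+ replicate 2 (0.0396). The fry test called the plasma cell (adjusted p = 0.00766) and thymic epithelial lists (0.0345).

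T cell receptor segments also differed between the thymus sorts. Beta chain segments Trbv1, Trbv13 and Trbv29, typical of mouse iNKT receptors, took 77.1% ± 3.14 of all Trbv counts in Fgd5+ libraries and 45.3% ± 1.39 in Fgd5- libraries (SD, n = 2), and 68.4% ± 3.62 in CD5+CD244- marrow. Alpha joining segments numbered above Traj18 took 22.7% ± 1.34 of Traj counts in Fgd5+ libraries, 40.9% ± 2.59 in Fgd5- libraries and 31.5% ± 0.059 in CD5+CD244- marrow. Those differences exceeded the spread between replicates, but no p is given since the design cannot reach a p below 0.333. Traj18, the joining segment of the invariant alpha chain, took 6.15% ± 1.51, 5.19% ± 0.354 and 7.69% ± 0.499, where the thymus difference lay within the replicate spread. Reads on Traj segments need not come from rearranged chains, so Traj shares are not shares of cells using a segment. All Trav segments together reached 25.3 ± 1.89 CPM in Fgd5+ and 132 ± 12.8 CPM in Fgd5- libraries. Trav11 and its copy Trav11d had 0 counts in every library, and 3 counts in a single library would be a share of up to 0.840% in Fgd5+, 0.196% in Fgd5- and 0.777% in CD5+CD244- libraries. Their transcripts are identical over 342 bases with 0 mismatches, so reads that fit both copies cannot be assigned, and this share says nothing about the invariant chain. CD5-CD244+ marrow libraries held under 1 CPM of Trbv and Traj counts on average and are left out.

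**Figure D2:**
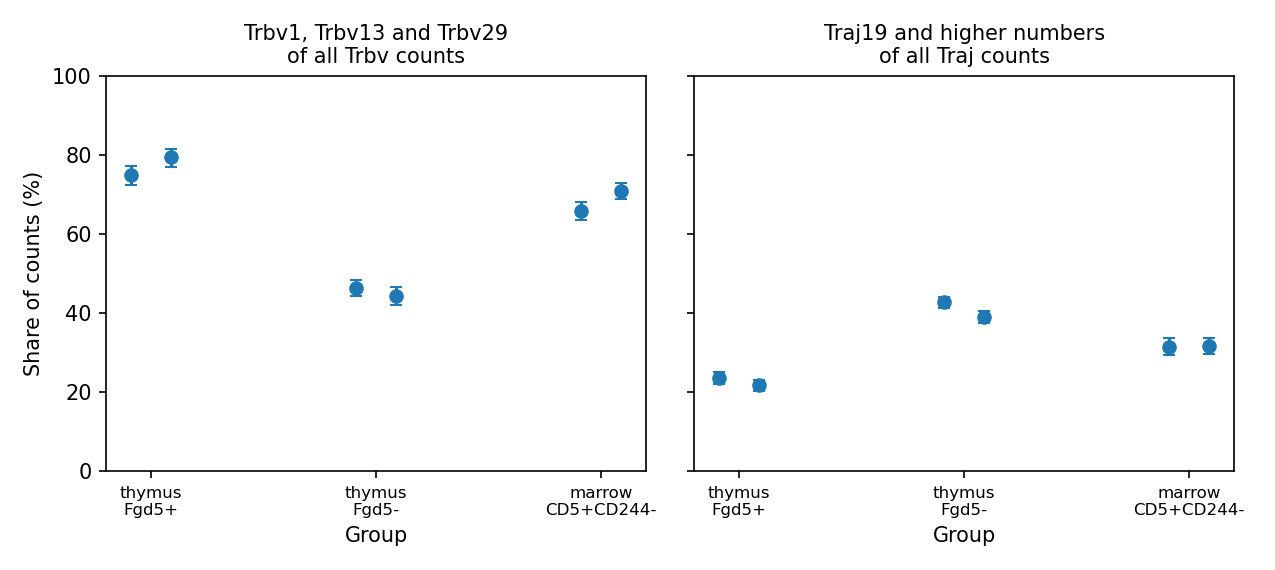
Share of T cell receptor segment counts, in percent, for each library of the Fgd5+ thymus, Fgd5- thymus and CD5+CD244- marrow groups. Points are libraries with 95% Wilson intervals, and the mean Trbv1, Trbv13 and Trbv29 share is 77.1% in Fgd5+ thymus, 45.3% in Fgd5- thymus and 68.4% in CD5+CD244- marrow.

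In the marrow, Cd5 and Cd244a followed the labels of the sort, and Fgd5 differed between the sorts. Cd5 (ENSMUSG00000024669, GRCm38 chromosome 19, 10717116 to 10739002) stood at 146 ± 3.45 CPM in CD5+CD244- libraries and 0.582 ± 0.323 CPM in CD5-CD244+ libraries (log2 fold change 7.97 ± 0.243), a surface protein of T cells. Cd244a (ENSMUSG00000004709, chromosome 1, 171559193 to 171609746), which overlaps Ly9 on the other strand, stood at 2.79 ± 0.969 against 176 ± 34.5 CPM (-5.98 ± 0.246). Fgd5 was 143 ± 6.92 against 36.4 ± 7.87 CPM, a log2 fold change of 1.98 ± 0.157 (edgeR adjusted p = 6.1e-06), although both groups were sorted as reporter-positive. Scaled to library totals, Fgd5 stood at 41.2 and 29.8 CPM in the CD5-CD244+ libraries, below the 50.5 and 52.1 CPM of the reporter-negative thymus libraries, which came from another run and were not tested against them. Ptprc had a log2 fold change of 0.16 ± 0.083 and did not pass (edgeR adjusted p = 0.170), but was called higher without CD5-CD244+ replicate 2 (0.0226). Procr, which encodes EPCR, was too low to test, with 0 and 0 counts in CD5+CD244- and 23 and 8 in CD5-CD244+ libraries.

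The marrow sorts differed by large folds in both directions. Cd40lg, the CD40 ligand of activated T cells, was 112 ± 5.60 against 0.125 ± 0.176 CPM (log2 fold change 9.76 ± 0.378). Themis (9.25 ± 0.307), Art2b (8.49 ± 0.515), Cd6 (7.89 ± 0.184) and Sit1 (7.51 ± 0.554) followed, and Tcrg-C1 had 1444 counts over both CD5+CD244- libraries and 3 over both CD5-CD244+ libraries (ratio 490, exact 95% counting interval 167 to 2377). In the other direction, Xirp1, Ip6k3, Epha4 and Rtn1 had 0 counts in CD5+CD244- libraries and were at least 344-fold, 300.2-fold, 289-fold and 240.2-fold lower there. Ace (ENSMUSG00000020681, chromosome 11, 105967945 to 105989964), angiotensin-converting enzyme, was 4.09 ± 2.39 against 2162 ± 176 CPM (-9.03 ± 0.429), and Nupr1 had a log2 fold change of -8.95 ± 0.317. EdgeR adjusted p-values of the 12 genes ran from 5.2e-09 for Cd6 to 3.1e-04 for Ace. Xirp1 overlaps the abundant Cx3cr1 on the same strand, and Themis and Ace have antisense models, so some of their reads may belong to the neighbour.

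Of 15992 genes tested in the marrow, 2812 were higher in CD5+CD244- and 3200 higher in CD5-CD244+ libraries. Libraries of the groups did not overlap at any of the 6012 called genes, and at 70.2% of all tested genes, against 33.3% by chance. The share of calls higher in CD5+CD244- was 46.8%, and 55.6% with GC content and length trends removed. That correction also moved the median of all genes to a log2 fold change of 0.11. Library composition differed as well. Mitochondrially encoded genes took 8.42% and 8.23% of counts in CD5+CD244- libraries and 5.95% and 5.69% in CD5-CD244+ libraries. Most of this was mitochondrial ribosomal RNA, with 7.61% and 7.48% of counts against 5.34% and 5.12%. The 10 most abundant genes took 19.0% and 20.5% against 14.4% and 13.7%. The models Gm26917 and Gm42418, at the ribosomal DNA repeat, took 5.60% and 6.87% against 3.10% and 3.14%.

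**Figure D3:**
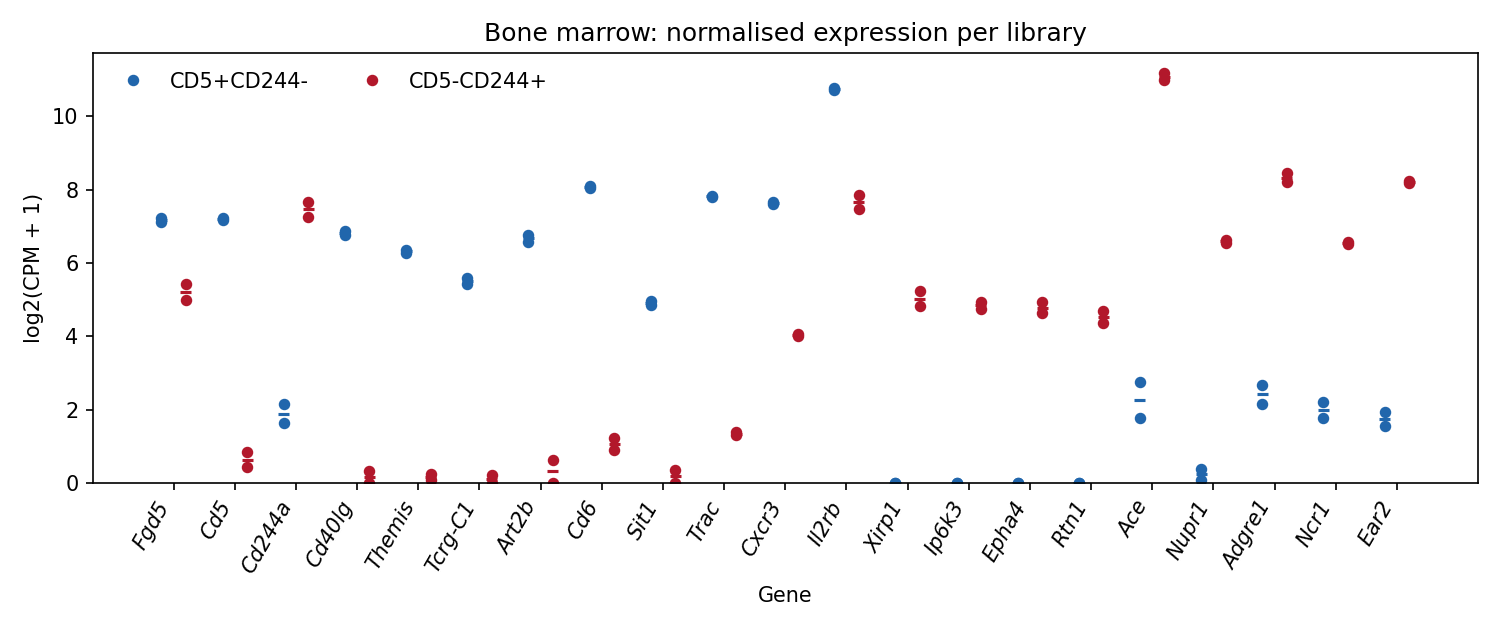
Normalised expression of named genes in the 4 marrow libraries, as log2(CPM + 1) with the gene on the x axis. Points are libraries and short lines are group means, and Cd40lg stands at 112 CPM in CD5+CD244- against 0.125 CPM in CD5-CD244+ while Ace stands at 4.09 against 2162 CPM.

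T cell lists rose in CD5+CD244- marrow cells. Of 22 genes of the T cell receptor complex and its signalling, 21 rose, 0 fell and 1 did not pass, and the same adjusted over the list alone. Cd3g rose from 11.4 ± 0.708 to 494 ± 15.6 CPM (log2 fold change 5.44 ± 0.118), Trac by 7.17 ± 0.157 and Bcl11b by 6.30 ± 0.136. Markers of iNKT1 cells rose in 15 of 15, also adjusted over the list alone, with Cxcr3 up by 3.69 ± 0.123 and Il2rb from 202 ± 38.1 to 1702 ± 47.2 CPM. Of 11 iNKT2 markers, 8 rose and 2 fell, with the same counts adjusted over the list alone. Gata3 rose by 3.92 ± 0.180, Izumo1r by 7.44 ± 0.349, and Lmo4 fell by 1.96 ± 0.134 on the log2 scale. Immature thymocyte markers had 7 of 16 higher and 3 lower (8 and 3 adjusted over the list alone). The members higher included Lef1 (4.10 ± 0.151) and Satb1 (3.54 ± 0.145), which T cells outside the thymus also express. The 3 members lower included Rag1 (-1.62 ± 0.400) and Sox4 (-1.44 ± 0.226). Gamma delta T and MAIT markers had 7 of 9 higher and 1 lower, with the same counts adjusted over the list alone, among them Tcrg-C2 (6.13 ± 0.317). Camera adjusted p-values were 1.1e-58 for the T cell receptor list, 2.6e-20 for iNKT1, 6.0e-05 for iNKT2 and for immature thymocyte markers, and 9.1e-05 for gamma delta T and MAIT markers. Each of these 5 lists had an adjusted p = 0.292 with an estimated correlation.

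Effector and NK genes split between the marrow sorts. Cytotoxic effectors had 13 of 23 higher in CD5+CD244-, 6 lower and 4 not passing, and 13 higher and 7 lower adjusted over the list alone (camera direction up, adjusted p = 0.00279; adjusted p = 0.469 with an estimated correlation). Klrk1, which encodes NKG2D, rose by 2.58 ± 0.113, Tnfsf10 by 3.25 ± 0.159 and Ctsw by 2.61 ± 0.131, while Lamp1 fell by 2.44 ± 0.119 on the log2 scale. Gzma, which rose in the thymus, was 1.48 ± 0.226 against 32.7 ± 12.1 CPM in the marrow. NK and ILC1 markers had 9 of 14 lower, 4 higher and 1 not passing, with the same counts adjusted over the list alone (camera adjusted p = 4.0e-04; adjusted p = 0.469 with an estimated correlation). Ncr1 had a log2 fold change of -4.95 ± 0.209 and Eomes of -5.68 ± 0.367. NK receptors had 17 of 30 higher, 9 lower and 4 not passing (18 and 9 adjusted over the list alone) and were not called (camera adjusted p = 0.0521). Their adaptor genes Fcer1g and Tyrobp fell by 3.64 ± 0.123 and 3.72 ± 0.130 on the log2 scale, and Klrb1c rose by 2.69 ± 0.118. Cd244a, on which the cells were sorted, was among the 9 lower members. The NK receptor list was called without CD5+CD244- replicate 1 (camera adjusted p = 0.0107), CD5+CD244- replicate 2 (0.00911) or CD5-CD244+ replicate 1 (0.00807), and by fry (0.0123).

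Myeloid and B cell genes were higher in CD5-CD244+ marrow cells. Monocyte and macrophage markers had 10 of 16 lower in CD5+CD244-, 2 higher and 4 not passing (11 lower and 2 higher adjusted over the list alone). Adgre1, which encodes F4/80, was 4.45 ± 1.37 against 321 ± 35.9 CPM, and Fcgr1 had a log2 fold change of -5.87 ± 0.394. Csf1r, the macrophage growth factor receptor gene, was 16.4 ± 6.40 against 2087 ± 130 CPM, while Ly6c2 rose by 2.65 ± 0.113. Dendritic cell markers had 8 of 13 lower and 1 higher (9 and 1 adjusted over the list alone), among them Itgax (-5.66 ± 0.158) and Cst3 (-4.46 ± 0.129). Camera gave an adjusted p of 1.0e-09 for monocyte and 1.6e-08 for dendritic cell markers, each with an adjusted p = 0.329 with an estimated correlation. B lineage markers had 12 of 15 lower and 0 higher (13 lower adjusted over the list alone), with Cd22, Spib and Pax5 lower by log2 fold changes of -2.03 ± 0.206, -2.02 ± 0.215 and -1.55 ± 0.166 (camera adjusted p = 0.00135; adjusted p = 0.294 with an estimated correlation). Neutrophil markers had 10 of 16 lower and 1 higher, with the same counts adjusted over the list alone (camera adjusted p = 0.00710; adjusted p = 0.647 with an estimated correlation) and were not called by fry (adjusted p = 0.112). Among them, Ngp was 641 ± 225 against 2305 ± 383 CPM and Gfi1 was the member higher.

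Immediate early and dissociation stress genes were lower in CD5+CD244- marrow cells, in 9 of 19 members with 1 higher and 9 not passing (11 lower and 1 higher adjusted over the list alone; camera adjusted p = 2.8e-04; adjusted p = 0.647 with an estimated correlation). Nr4a1 was 18.9 ± 3.22 against 1226 ± 208 CPM, Zfp36 fell by 2.81 ± 0.215 and Fos by 2.21 ± 0.181 on the log2 scale, and Nr4a3 rose by 2.21 ± 0.272. The fry test did not call this list (adjusted p = 0.0646). Because the sorts also differed in T cell and myeloid genes, a stress difference cannot be told apart from a difference in cell type.

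The other marrow lists were not called. Stem and progenitor markers had 13 of 20 lower and 4 higher, with the same counts adjusted over the list alone, among them Meis1 (-4.13 ± 0.341) and Lmo2 (-2.87 ± 0.255). Tissue residency and egress genes had 8 of 16 higher and 6 lower (9 and 6 adjusted over the list alone), with Zfp683 at 303 ± 11.2 against 4.52 ± 1.98 CPM and S1pr5 at 1.58 ± 0.360 against 311 ± 9.36 CPM. Markers of iNKT17 cells had 6 of 12 higher and 2 lower (6 and 3 adjusted over the list alone), with Rora up by 3.48 ± 0.138. Eosinophil markers had 1 of 9 lower, Ear2 (2.39 ± 0.614 against 292 ± 6.80 CPM), and the same count adjusted over the list alone. Erythroid markers had 5 of 13 lower, basophil and mast cell markers 5 of 11 lower and 1 higher, and megakaryocyte markers 1 of 7 lower and 1 higher. Adjusted over the list alone, these counts were 5, then 6 and 1, then 1 and 1. Endothelial and stromal markers had 2 of 8 lower, plasma cell markers 2 of 6 lower and thymic epithelial markers 1 of 2 lower, with the same counts adjusted over the list alone. Proliferation genes had 9 of 20 lower and 1 higher, also adjusted over the list alone, where Mki67 fell by 0.66 ± 0.087 on the log2 scale. Interferon-stimulated genes had 7 of 18 higher and 2 lower, also adjusted over the list alone, with Ifit1 up by 2.74 ± 0.250. Inhibitory receptors had 4 of 10 higher and 2 lower (5 and 2 adjusted over the list alone), with Btla up by 2.63 ± 0.157 and a log2 fold change of -6.80 ± 0.281 for Havcr2. Cd244a, on which the cells were sorted, was among the 2 lower members. Camera adjusted p-values of these lists lay between 0.0572 for eosinophil markers and 0.912 for residency genes. Endothelial markers were called whichever single marrow library was left out (camera adjusted p between 0.00132 and 0.0441) and by fry (0.00632), which also called iNKT17 markers (0.0303). Other lists here were called by camera when single libraries were left out. Without CD5+CD244- replicate 1 these were erythroid (adjusted p = 1.1e-04), interferon (0.00664), stem and progenitor (0.0105), basophil and mast cell (0.0107) and eosinophil (0.0159) lists. Without CD5+CD244- replicate 2 they were erythroid (0.0386), basophil and mast cell (0.0432) and stem and progenitor (0.0441) lists. Without CD5-CD244+ replicate 1 they were basophil and mast cell (0.0247) and interferon (0.0266) lists, and without CD5-CD244+ replicate 2 eosinophil (0.00268) and erythroid (0.00510) lists. Eosinophil markers were also called with GC content and length trends removed (0.0335).

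**Figure D4:**
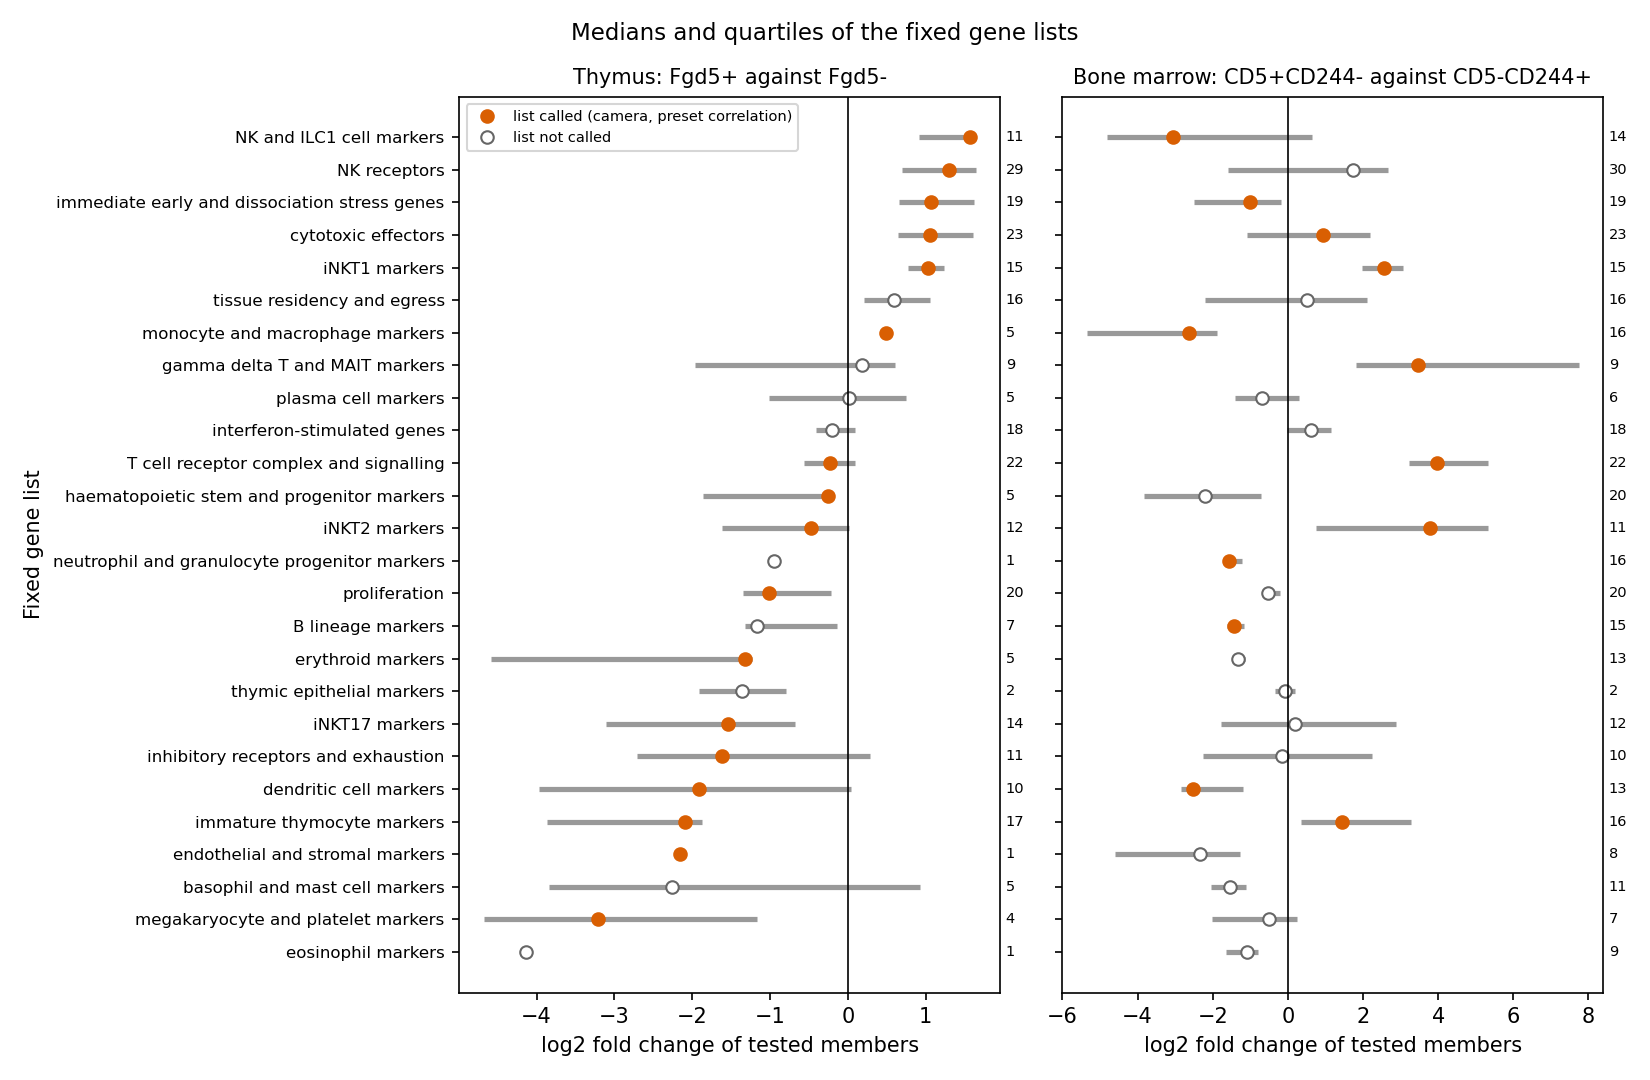
Median log2 fold change of the tested members of each fixed gene list, with the thymus on the left and the marrow on the right. Bars span the quartiles, numbers at the right are members tested and filled points are lists called by camera at the preset correlation, with a thymus median of -2.09 for immature thymocyte markers and a marrow median of 3.97 for the T cell receptor list among them.

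The thymus and marrow contrasts were then compared over the 13934 genes tested in both, asking whether genes that part the thymus sorts also part the marrow sorts. Genes higher in Fgd5+ thymus and in CD5+CD244- marrow numbered 475, against 196 for independent lists (Fisher's exact test, two-sided, odds ratio 4.31, 95% interval 3.76 to 4.93, adjusted p = 8.6e-96 over 4 tests). Among them were Ifng, Gem, Fgd5, Klre1 and Klra1. Genes lower in both numbered 285 against 155 (odds ratio 2.39, exact adjusted p = 1.3e-27), among them Ifngr2, whose marrow log2 fold change was -4.78 ± 0.194. Opposite directions were also above the level of independent lists, with 249 genes higher in Fgd5+ and lower in CD5+CD244- against 170.2 (odds ratio 1.69, exact adjusted p = 7.8e-11) and 231 the other way against 179 (odds ratio 1.43, exact adjusted p = 1.2e-05). These p-values treat genes as independent, which genes regulated together are not, so they overstate the evidence. The level for independent lists also takes every gene as equally likely to be called, whereas genes with more counts are easier to call in both tissues. How much of the excess in all 4 pairs of directions comes from this was not tested. In total 760 genes went the same way and 480 opposite ways. Log2 fold changes correlated across genes at a Pearson r of 0.114 and a Spearman correlation of 0.105, given without a p. The contrasts share no library.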

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

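Thinning to the smallest library and the offsets for GC content and length were chosen after seeing the data. Across every alternative run, 69 of 102 genes named by the rule in the thymus and 93 of 113 in the marrow kept their direction and their side of the threshold. Receptor shares have no test, and with 2 libraries per group leaving 1 out says nothing about their stability. Of the list tests, 4 of 26 in the thymus beside the cytotoxic list and 6 of 27 in the marrow did so. An estimated correlation called 0 lists in the thymus and 0 in the marrow, ending 16 and 12 of these calls, and gave the thymus cytotoxic effectors list an adjusted p of 0.140. With 4 libraries that correlation, and the test made with it, rest on few degrees of freedom. Some ended calls had an estimated correlation below the preset 0.01, such as thymus immature thymocyte markers (-0.0143) and the T cell receptor list (-0.0188). The thymus endothelial list, with 1 tested member, had no estimate. The ended calls are therefore not evidence of correlation between genes. The fry test ended 4 and added 3 list calls in the thymus, and ended 2 and added 4 in the marrow, and the libraries left out changed others. A threshold of 0.01 left 579 thymus genes higher and 550 lower, and 1813 marrow genes higher in CD5+CD244-, which follows from the stricter threshold. An unadjusted p under 0.05 in both tissues raised the cross-tissue overlap of calls from 760 to 1387. Leaving out single libraries, where the lone library is assumed to vary like the others, gave 637 to 1614 genes lower in the thymus and 15 to 19 called lists in the marrow, the latter against 12 with all libraries, and the cause was not tested. Genes higher in the thymus ranged from 694 to 1400, its called lists from 14 to 16 and its cytotoxic list from an adjusted p of 2.5e-20 to 1.7e-12. Some changes that were not called with all libraries turned direction, and the cause was not tested. Ptprc in the thymus went to a log2 fold change of 0.0059 with GC content and length offsets. Over the single libraries left out in the thymus, the log2 fold change of Alas2 in thymus libraries ranged from -3.62 to 0.37 and that of Hbb-bs from -5.42 to 1.00, both highest without Fgd5- replicate 1. In the marrow, Ear6 ranged from -4.48 to 0.16, the latter without CD5-CD244+ replicate 1, and Epcam from -0.32 to 2.31, the former without CD5-CD244+ replicate 2. With the shared replicate number as a block, 1216 genes were higher and 1179 lower in the thymus, and 2950 and 3351 in the marrow. The block called 18 thymus and 15 marrow lists, adding the thymus residency and egress list (camera adjusted p = 0.00986) and the marrow NK receptor (0.0374), erythroid (0.00615) and endothelial (0.00615) lists, and gave Igfbp4 in the thymus an edgeR adjusted p of 0.180. Deviations of libraries sharing a number correlated at 0.0689 in the thymus and 0.056 in the marrow, and no label says that a number marks a shared animal, so the numbers were not taken as pairs. A fit of all 8 libraries called 849 genes higher and 953 lower in the thymus, where DESeq2 called 987 and 1004 and limma-voom 1131 and 932.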

Other observations

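The genes of this and the next paragraph, and all tests below except those for GC content and length, were chosen after their values were seen. In the thymus, cytokine receptor genes went in different directions in Fgd5+ cells. Il12rb2 rose from 110 ± 1.48 to 237 ± 8.10 CPM and Il18rap, a subunit of the IL-18 receptor, from 209 ± 28.2 to 460.4 ± 38.8 CPM (n = 2). The other interferon gamma receptor chain, Ifngr1, rose by a log2 fold change of 0.73 ± 0.083, unlike Ifngr2. The IL-6 receptor genes Il6ra and Il6st had log2 fold changes of -3.72 ± 0.273 and -2.46 ± 0.100. Among transcription factors, Bhlhe40 rose by 1.61 ± 0.115 and Klf4 by 1.88 ± 0.182, while Bach2 had -1.87 ± 0.102 and Myb -2.38 ± 0.138. All 3 tested Fgd family genes were higher in Fgd5+ cells, with log2 fold changes from 0.31 to 1.79. The highest was Fgd5 itself, on whose reporter the cells were sorted. In the marrow, 1 of 5 tested Fgd family genes was higher in CD5+CD244- cells and 3 were lower. Fgd5 was still counted at 49.9 CPM in the Fgd5- thymus libraries.

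In the marrow, 8 of 8 tested Gimap genes, GTPases of lymphocytes, were higher in CD5+CD244- cells, with a median log2 fold change of 3.36 and a highest of 4.30, and Gimap3 reached 1216 ± 62.9 CPM. Of 8 tested Cd300 genes, 8 were lower, with log2 fold changes from -9.02 to -1.61. Il21r and Il27ra rose by 3.60 ± 0.135 and 3.68 ± 0.131. Lrp1 was 27.7 ± 8.01 against 2271 ± 20.9 CPM, and Treml4 had a log2 fold change of -7.21 ± 0.230. The 2 CD5-CD244+ libraries differed in the collagen genes Col1a1 (104 and 908 CPM) and Col1a2 (35.1 and 416 CPM).

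Immature thymocyte genes were lower in Fgd5+ thymus libraries. Removing GC content and length trends left 13 of 13 called members called, with a median log2 fold change of -2.24 before and -2.19 after, which argues against that bias as the whole cause. The share of Trbv1, Trbv13 and Trbv29 in Fgd5- libraries minus that in Fgd5+ libraries was -31.8 percentage points, with a spread of 3.14. T cells of another lineage or stage in the Fgd5- gate may therefore account for part of the difference, although that gate required CD1d and NK1.1 staining. A difference between Fgd5+ and Fgd5- cells of the same lineage stays open and was not tested.

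NK receptor and cytotoxic genes were higher in Fgd5+ thymus libraries, and 35 of 35 called members stayed called with GC content and length trends removed. Of these, 22 lay outside the Klra, Klrb and Klrc families, 15 of them with a log2 fold change above 1, so shared reads among those families could not make the whole pattern. Eomes had a log2 fold change of -7.13 ± 0.625, which argues against Eomes-expressing NK cells in the Fgd5+ gate. The changes differed among members by 14.3 per degree of freedom, above the 95% point of 1.43. A uniform dilution of the same cells in the Fgd5- gate predicts equal changes only if the diluting cells lack RNA of these genes. That RNA was not measured, so the spread does not decide on dilution, which stays open. Trbv1, Trbv13 and Trbv29 took 77.1% of Trbv counts in Fgd5+ and 45.3% in Fgd5- libraries. Other T cells in the Fgd5- gate are therefore a mixture that could lower these genes there. Such mixtures and a biological difference between the sorts stay open, and neither was tested. Stress genes rose in the same libraries (7 of 19 higher, 1 lower), and whether they share a cause with this pattern was not tested.

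Of the neutrophil, erythroid and B lineage markers, 27 were called lower in CD5+CD244- marrow libraries, although the erythroid list itself was not called (camera adjusted p = 0.121), with 8 of its 13 members not passing. That list was called without CD5+CD244- replicate 1 (1.1e-04), CD5+CD244- replicate 2 (0.0386) or CD5-CD244+ replicate 2 (0.00510). With GC content and length trends removed, 26 of 27 called members stayed called, with a median log2 fold change of -1.45 before and -1.33 after. The medians of the 3 lists lay within 0.257 of each other, while the widest quartile range of a list was 0.503. These lists were grouped after their medians were seen, so that closeness decides nothing. Carry-over of RNA or cells from other marrow cells and lower expression in the sorted cells themselves both stay open.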
